A study of Mus musculus with 3 samples.

How the data were processed

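The data were 3 2-colour Agilent mouse expression arrays, each with RNA of a Hopx-null and a Hopx-heterozygous culture of embryoid bodies at day 8. Per the labels' protocols, stem cells were derived from blastocysts and kept on feeder cells, embryoid bodies were formed in hanging drops of 20 µl, and the cardiac medium held VEGF at 5 ng/ml, bFGF at 10 ng/ml, FGF10 at 12.5 ng/ml, 1 mM ascorbic acid and 2 mM Glutamax. Labelling started from 200 ng of total RNA.

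The scanner's spot intensity values in both channels, with local backgrounds, flags and the scanner software's own processed signals, were deposited as made by Agilent Feature Extraction 11.5.1.1 per the file headers, while the submitters' processing notes name version 8.5.1.1. The authors deposited a table of processed values whose scale is not stated, and which was read as log2 ratios of the same arrays with replicate 3 turned. This was because, set against the scanner ratios of bright spots (mean log2 intensity above 11), it had slopes of 0.946, 0.953 and -0.948. The medians of its columns were -0.10, -0.11 and 0.07. How it was normalized and centred is not known. The scanner files' log10 ratio column, made by the scanner software per the file headers, was not used. All 3 arrays came from 1 slide and 1 scan, so neither could be used as a block.

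The foreground medians were used because the design, fixed before the data were examined, named mean foreground signals, which the scanner files used here do not hold. With limma 3.58.1 in R 4.3.3, backgrounds were corrected by normexp with an offset of 50 and log2 ratios normalized by loess within each array, with control and outlier spots at weight 0. Outlier spots were left out, saturated spots were kept, and spots of a probe were averaged. The ratios of replicate 3 were turned, a departure from the fixed design, which took Cy5 as null on all arrays. Once turned, the group holds both dye orientations, 2 arrays against 1, so a dye effect does not cancel fully. Probes had to be well above background in the null channel on all 3 arrays or in the heterozygous channel on all 3, which kept 24552 of 39429. Each probe's ratio was tested against 0 with lmFit and eBayes and adjusted by Benjamini-Hochberg over the probes kept, and a gene was given its brightest probe. Every SE given is the moderated SE of eBayes, which shares spread between probes. It can be smaller or larger than the arrays' own spread alone would give. For Myh6 and Nkx2-5, with moderated SEs of 0.14 and 0.15, the SD over the 3 arrays was 0.42 and 0.44. Beside a fold bound ("at least"), the dim channel was set on each array to the higher of the lowest signal among probes well above background and the probe's own signal, after loess and Aquantile. For T its own signal was the higher on all 3 arrays, so that its bound equals its fitted ratio, and such bounds are open to dye bias.

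Probes were named through unversioned accessions in a RefSeq gene table (GRCm38.p6), which named 28025 of 39429 probes (71.1%). The array design is on build mm9 per the file headers, so no coordinates of that table are printed. It served for names, for the chromosome of a gene and for neighbours. Probes without a match kept the accession of the array.

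The 29 gene lists were written before the data were examined, and 27 had at least 5 measured members. They were tested with camera at a preset correlation of 0.01 (two-sided, adjusted over the lists), with an estimated correlation and with fry as alternatives. fry's directional test asks whether a list's genes move on balance in a single direction and its mixed test whether they change in either. Neither compares a list with the other genes, as camera does, so fry and camera answer different questions. The genes named in the text are Hopx, the 12 with the largest and the 12 with the smallest ratio among calls of equal sign on all 3 arrays (clone names, predicted models and accessions left out), up to 3 called members of each list with the largest change (or 2 with the smallest adjusted p where none passed), and Nkx2-5, Myh6, Tnnt2, Nppa, Isl1, Axin2, Lef1, Bmp4, Id1, Pou5f1, Xist and Ddx3y. Xist was not among the genes tested. Rnf43, the Wnt target that fell most, is named outside this rule and is not in the counts of named genes.

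The test was tried on simulated ratios with the spread of these arrays, 200 of 24552 probes being changed. It called 48.0% of probes changed by 0.5 on the log2 scale, and all 50 changed by 1, all 50 changed by 2 and all 50 changed by 3, and 4.40% of calls were false. The simulated probes varied independently, and on the arrays themselves 60.3% of the genes tested were called. Adjusted p-values depend on the share changed, so the simulated recovery and false share do not carry over to the real calls. Over 304 probes with 10 spots each, the median SD between single spots of an array was 0.0756, and the median SD between the 3 arrays' means of 10 spots, which holds biological spread as well, was 0.107. These SDs are unlike measures, since a mean of 10 spots varies less than a single spot. The variance between these means was at the median 21.3 times that expected from the spots alone, and above it for 94.7% of these probes. Alternatives for background, normalization, filter, variance, replicates, probe rule and list test were fixed before the data were examined. Leaving replicate 3 as labelled, a dye term in the fit and limma's treat against a 1.5-fold change were added after.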

Results

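Gene expression was compared between mouse embryoid bodies lacking Hopx (Hopx-/-, called null) and embryoid bodies with 1 working copy of the gene (Hopx+/-, called heterozygous) after 8 days of cardiac differentiation. Hopx encodes a small homeodomain protein found in heart and progenitor cells, and the series asked what part it plays in commitment to muscle. Embryoid bodies are aggregates of embryonic stem cells that form derivatives of several germ layers. Each of 3 biological replicates was a 2-colour Agilent array carrying RNA of a null and of a heterozygous culture, so that every ratio was measured within an array. Between 61.9% and 72.9% of the 43020 non-control spots were well above background in a given channel, and the number of arrays limits the precision. The labels do not say whether the replicates were separate stem cell lines or separate differentiations of the same lines, so p-values measure the spread between these samples. The difference between genotypes cannot be parted from a difference between lines.

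All signed values below are null over heterozygous with replicate 3 turned, because its direction is not settled by the labels. The labels give Cy5 to the null culture on all 3 arrays. Yet across probes the ratios of replicate 3 correlated at r = -0.903 with replicate 1 and r = -0.901 with replicate 2, while replicates 1 and 2 correlated at r = 0.939 (probes are not independent replicates). In the authors' own deposited value table replicate 3 runs the other way from its scanner ratios (r = -0.867, against r = 0.929 and r = 0.919 for replicates 1 and 2). The direction of that table was taken. With replicate 3 left as labelled, limma called 0 genes at adjusted p under 0.05, and 75 genes had an unadjusted p under 0.05. From replicates 1 and 2 alone, whose direction is not in doubt, limma called 11856 genes.

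In null embryoid bodies most measured genes of the heart's contractile apparatus and of endoderm fell, and most of early mesoderm, pluripotency, blood and neuroectoderm rose. Camera called these 6 lists with its preset correlation and none of them with an estimated correlation (adjusted p from 0.225 to 0.412 with an estimated correlation). Hopx itself fell by 3.13 on the log2 scale (SE 0.11, n = 3 arrays, adjusted p = 2.8e-07 by limma), an 8.76-fold lower signal, with array values of -2.98, -2.97 and -3.45. Its other probe fell by 2.53 (SE 0.13). Both Hopx probes were well above background in the null channel on all 3 arrays, and where they lie relative to the inactivated part of the gene is not given in the sources used here. Myh6, the alpha cardiac myosin heavy chain, fell by 5.31 (SE 0.14, n = 3), and Mesp1, a transcription factor of the earliest cardiac mesoderm, rose by 3.76 (SE 0.09, n = 3).

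Of 19802 genes tested, 11943 changed at adjusted p under 0.05, 5977 higher and 5966 lower in null cultures. A gene name was found for 14883 of the 19802. The others are accessions of the array, so a gene may be counted more than once. A change of at least 2-fold was seen for 964 genes that rose and 1194 that fell, and of at least 8-fold for 22 that rose and 39 that fell. The 12 named genes that fell most were Myh6, Myh7, Srgn, Myl4, Cox6a2, Slco2a1, Cubn, Myl7, Myl3, Mybpc3, Cck and Fxyd3, from -5.31 to -3.76. The 12 that rose most were Trh, Calca, Pf4, Mesp1, Fgf5, Slc27a2, Rbbp9, Cer1, Olig1, Pou3f1, Prim2 and Magohb, with Magohb at 3.20. Cer1 and Olig1 were well above background in the heterozygous channel on 2 of the 3 arrays. For Rbbp9, another probe was called in the opposite direction, as for 20 of the 480 genes with several probes and a change of at least 2-fold. The numbers of calls rest on the settings: centring on the median without loess gave 73.9% of calls higher, against 50.0% in the main setting, with the median of all genes at 0.23. An ordinary t statistic per probe called 3998 genes, with 26 of the 105 named genes losing their call, among them Nkx2-5, Tnnt2, T, Nanog, Slc4a1, Hba-x, Myb, Zic2, Col1a2, Bmp4 and Axin2.

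**Figure D1:**
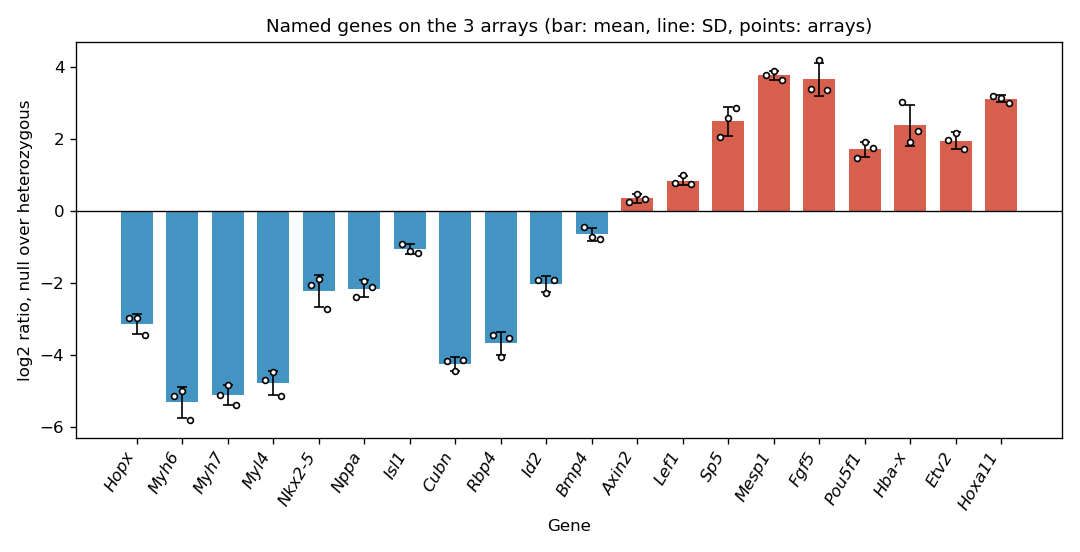
Log2 ratio of null over heterozygous embryoid bodies for 20 named genes, with the mean of the 3 arrays as a bar, the SD as a line and each array as a point. Hopx lies at -3.13, Myh6 at -5.31 and Mesp1 at 3.76, and the 3 arrays lie on the same side of 0 for every gene drawn.

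The heart's contractile apparatus fell almost as a whole. Of 26 measured genes of the cardiac sarcomere, 25 fell and 0 rose, with a median of -2.40 (adjusted p = 1.4e-13 by camera, and adjusted p = 0.357 with an estimated correlation), and 25 fell when adjusted over the list alone. The median was -3.12 with the scanner software's processed signals and -1.79 without the filter on dim probes. Myh7, the beta cardiac myosin heavy chain, fell by 5.11 (SE 0.11), and Myl4, an atrial myosin light chain, fell by 4.77 (SE 0.12). Tnnt2, cardiac troponin T, was measured on 2 arrays and fell by 2.73 (SE 0.17). Of 23 genes for calcium handling, conduction and cardiac hormones, 16 fell and 2 rose (camera adjusted p = 0.00025, and adjusted p = 0.330 with an estimated correlation), and 16 fell and 3 rose adjusted over the list alone. Cox6a2, the heart and muscle form of a cytochrome oxidase subunit, fell by 4.40 (SE 0.12), Ryr2, the cardiac calcium release channel, by 2.23 (SE 0.13), and Nppa, encoding atrial natriuretic peptide, by 2.16 (SE 0.10).

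Of 24 measured cardiac transcription factors, 12 fell, 4 rose and 8 did not pass (median -0.24, or 0.00083 with median centring without loess, where the median of all genes was 0.23, camera adjusted p = 0.0162, and adjusted p = 0.357 with an estimated correlation), the same counts as adjusted over the list alone. Myocd, a coactivator of muscle genes, fell by 2.88 (SE 0.10), Nkx2-5, a core cardiac factor, by 2.23 (SE 0.15), and Irx4, a ventricular factor, by 1.86 (SE 0.08). Genes of the second heart field and cardiac progenitors went both ways: 10 fell and 7 rose of 24, and the list did not pass (median -0.04, or 0.21 with median centring without loess, camera adjusted p = 0.837), with the same counts adjusted over the list alone. That list includes Hopx, and in it Isl1, a progenitor factor, fell by 1.06 (SE 0.09), Aldh1a2, which makes retinoic acid, rose by 2.51 (SE 0.10), and Nr2f1, a factor of atrial identity, rose by 2.30 (SE 0.10).

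Genes of stages that precede the heart were higher in null cultures. Of 19 genes of the primitive streak and early mesoderm, 16 rose and 0 fell (median ratio of null over heterozygous 2.82, camera adjusted p = 3.7e-07, and adjusted p = 0.357 with an estimated correlation), and 16 rose adjusted over the list alone. The median ratio was 4.70 with processed signals, 2.30 without the filter on dim probes and 2.23 in the authors' value table. T, the mesoderm factor Brachyury, was not well above background in the heterozygous channel on any array, and its bound was at least 6.72-fold higher in null cultures (limma adjusted p = 1.5e-05), as a mean over arrays with log2 ratios of 1.90, 3.26 and 3.08. Of 30 pluripotency genes, 20 rose and 6 fell, 5 of these by at least 2-fold (median 0.92, camera adjusted p = 0.0019, and adjusted p = 0.412 with an estimated correlation), and these counts held adjusted over the list alone. Pou5f1, which encodes Oct4, rose by 1.71 (SE 0.10), L1td1 by 2.06 (SE 0.08) and Nanog by 2.01 (SE 0.14), while Tfcp2l1, a factor of naive pluripotency, fell by 2.23 (SE 0.14). For Nanog, another probe was called in the opposite direction.

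Of 31 Bmp and Smad genes, of a pathway that patterns mesoderm, 22 fell and 5 rose (median -0.55, or -0.24 with median centring without loess, camera adjusted p = 0.00062, and adjusted p = 0.308 with an estimated correlation), with the same counts adjusted over the list alone. Id2, a direct Bmp target, fell by 2.03 (SE 0.10), Bmpr2, a Bmp receptor, by 1.33 (SE 0.08) and Smad9 by 1.30 (SE 0.09). Bmp4 fell by 0.65 (SE 0.09) and Id1 by 0.60 (SE 0.08), and both lost their call with median centring without loess (adjusted p = 0.199 and 0.212). Of 31 Wnt targets, 15 rose and 8 fell, and the list did not pass (median 0.21, camera adjusted p = 0.108), with the same counts adjusted over the list alone. The size of that median is not firm, at 0.13 without replicate 1, 0.08 in the authors' value table and 0.45 with median centring without loess. By at least 2-fold, 6 of these targets rose and 4 fell, with Rnf43 lowest at -2.08 (SE 0.09) and Jun at -1.69 (SE 0.12). Sp5 and Sp8 rose by 2.49 (SE 0.14) and 2.62 (SE 0.13), and Lef1, a nuclear partner of beta-catenin, by 0.84 (SE 0.09). Axin2, a feedback target, rose by 0.35 (SE 0.09, adjusted p = 0.0081) and lost its call without replicate 2 (adjusted p = 0.0730). Its probe was dim, at a mean log2 intensity of 6.49. It was well above background in the heterozygous channel on 2 of the 3 arrays, so the size of its rise is not firm. Of 39 Wnt ligands, receptors and secreted inhibitors, 18 rose and 10 fell without the list passing (camera adjusted p = 0.106), though it passed with the channels as separate samples and no replicate block (adjusted p = 0.0442). Wnt5b rose by 2.67 (SE 0.08) and the inhibitors Sfrp1 and Sfrp2 rose by 2.53 (SE 0.09) and 1.93 (SE 0.09). Of 17 Notch pathway genes, 7 rose and 3 fell (camera adjusted p = 0.201).

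Endoderm genes also fell almost as a whole. Of 31 measured, 29 fell and 0 rose (median -1.92, camera adjusted p = 5.1e-14, and adjusted p = 0.225 with an estimated correlation), and 29 fell adjusted over the list alone. Cubn and Amn, which encode the partners of a visceral endoderm uptake receptor, fell by 4.25 (SE 0.10) and 3.14 (SE 0.09), and Rbp4, a retinol carrier, by 3.68 (SE 0.12). In the list of parietal endoderm and trophoblast, 15 of 20 fell and 1 rose (camera adjusted p = 4.3e-05, and adjusted p = 0.357 with an estimated correlation), among them Srgn at -4.98 (SE 0.10) and Lama1, a basement membrane laminin chain, at -2.56 (SE 0.08).

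Blood, endothelial and neural genes were higher in null cultures. Of 26 embryonic blood genes, 23 rose and 2 fell (median 1.64, camera adjusted p = 2.1e-08, and adjusted p = 0.357 with an estimated correlation), and 23 rose adjusted over the list alone. The median was 2.33 with processed signals. Slc4a1, the red cell anion exchanger, rose by 2.61 (SE 0.18), Hba-x, an embryonic globin, by 2.38 (SE 0.18), and Myb by 2.34 (SE 0.16). Of 28 endothelial genes, 21 rose and 4 fell (median 0.73, camera adjusted p = 9.5e-05, and adjusted p = 0.412 with an estimated correlation), with Etv2, a factor of the blood and vessel lineage, up by 1.95 (SE 0.10). Of 28 neuroectoderm genes, 20 rose and 2 fell (median 0.72, or 0.28 without the filter on dim probes and 1.52 with processed signals, camera adjusted p = 1.6e-05, and adjusted p = 0.357 with an estimated correlation), with Zic2 up by 2.60 (SE 0.16), Tubb3, a neuronal tubulin, by 2.29 (SE 0.11), and Sox3 by 2.22 (SE 0.12).

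Other mesodermal lists did not pass as wholes, though members moved. Of 16 smooth muscle genes, 5 rose and 5 fell (camera adjusted p = 0.755), with Actg2 up by 1.95 (SE 0.10) and Des, encoding desmin, down at -1.19 (SE 0.09). Of 16 skeletal muscle genes, 8 rose and 4 fell (camera adjusted p = 0.543), and the median of 0.21 and the mean of -0.03 differ in sign because Myl1 and Myh8 fell by 2.83 (SE 0.09) and 2.47 (SE 0.08). The median was 0.07 without the filter on dim probes and 0.03 in the authors' value table. Fibroblast and feeder genes, which the feeder layer of the stem cells could also supply, rose for 11 and fell for 4 of 22 (camera adjusted p = 0.136, and 0.0113 without replicate 2), led by Col1a2 at 1.59 (SE 0.16). Adjusted over the list alone, the counts were the same for every list whose count so adjusted is not given, except fibroblast and feeder (12 rose), neural crest (7 fell), cartilage and bone (5 fell) and stress genes (13 fell). In all, camera with the preset correlation called 7 lists higher and 8 lower of 27. With an estimated correlation it called 0, which with 3 arrays rests on few degrees of freedom. The estimate was 0.66 for the cardiac sarcomere, 0.41 for embryonic blood and 0.34 for early mesoderm. These lie far above the preset 0.01, so p-values at the preset may be much too small for these lists. For Hox and cell cycle genes the estimate was -0.015 each, and their calls were lost as well.

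**Figure D2:**
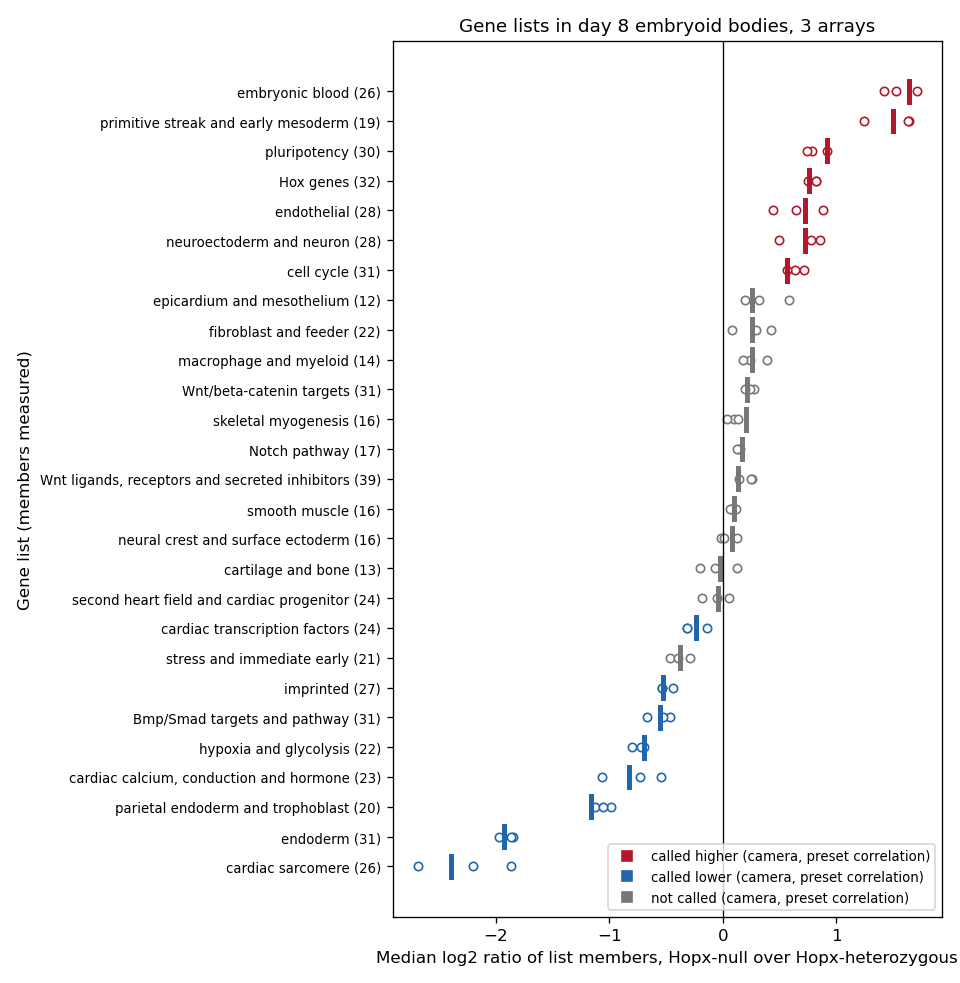
Median log2 ratio of null over heterozygous embryoid bodies for the 27 gene lists tested, as a bar for the mean ratio and an open circle for each of the 3 arrays, coloured by camera's call with the preset correlation. The cardiac sarcomere list lies lowest at -2.40 and embryonic blood highest at 1.64.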

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

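Leaving replicate 3 as labelled, a dye term and limma's treat were added after the data were seen, and the cause of a change was not tested unless given. Every called list kept its call and direction under the other alternatives for background, normalization, filter, variance, replicates, pairing and probe rule, and Hopx kept its call in all but replicate 3 as labelled. Without any replicate in turn, 9777 to 11856 genes were called. Of the 2158 genes changed at least 2-fold, 2138 or more were called in the same direction under each such alternative, except 1511 with the ordinary t statistic, which does not share spread between probes, and 2044 of 2044 tested when both channels had to be above background. With the scanner software's processed signals, 2191 genes rose and 2247 fell at least 2-fold. Median centring without loess moved the median of all genes to 0.23 and gave 3015 genes lower, with 2040 higher and 673 lower at least 2-fold. In the authors' deposited values, 3910 genes were higher (630 by at least 2-fold), and the smallest correlation between arrays was 0.784 over the kept probes (0.702 over all non-control spots). The ordinary t statistic called 3998 genes (1964 higher, 2034 lower), treat against 1.5-fold called 2720 (1263 higher, 1457 lower), and asking for at least 2-fold left 2158 (964 higher, 1194 lower), by construction. Of 105 named genes, 26 lost their call with the ordinary t statistic and 2 each in the authors' table (Ftx, Axin2), with median centring (Bmp4, Id1) and with the channels as separate samples with no replicate block (Alpl, Axin2), and Axin2 also without replicate 2.

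With replicate 3 as labelled, limma called 0 genes (0 higher, 0 lower, 0 and 0 at least 2-fold), the lowest correlation was -0.902, 7 lists passed, and the cardiac sarcomere and Bmp lists lost their call at medians of -0.57 and -0.10, Hopx at -0.83, and Tnnt2 stood at 0.35. This follows from a single array of opposite sign. Camera with an estimated correlation called 0 lists, the cardiac sarcomere (median -2.40) and Bmp (median -0.55) lists among those lost, while fry's directional test called 22 and its mixed test all 27. fry does not compare a list with the other genes. With 60.3% of the genes tested called, most lists were bound to pass the mixed test, whose passes single out no list. Wnt ligands, Notch, macrophage, epicardium and stress lists, not called by camera in the main setting, passed the directional test. Wnt targets (median 0.21) passed fry's directional and mixed tests, and fry called skeletal muscle lower (median 0.21), opposite to the direction camera gave it. Signal over background limits what dim probes can show, and 61.9% to 72.9% of spots were well above it. No slide or scan block was run, since all arrays share 1 slide and 1 scan.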

Other observations

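Several further groups moved in null cultures. Of 32 Hox genes, which mark position along the body axis, 26 rose and 1 fell (median 0.76, or 1.37 with the scanner software's processed signals and 1.01 with median centring without loess, camera adjusted p = 5.2e-08, and adjusted p = 0.225 with an estimated correlation), and 26 rose adjusted over the list alone. Hoxa11 rose by 3.11 (SE 0.08), Hoxd11 by 1.76 (SE 0.09) and Hoxd10, well above background in the heterozygous channel on 2 arrays, by 1.76 (SE 0.10). Of 31 cell cycle genes, 25 rose and 0 fell (median 0.56, or 0.97 with median centring without loess, camera adjusted p = 5.7e-08, and adjusted p = 0.225 with an estimated correlation), and 29 rose adjusted over the list alone. Mcm3 and Mcm5, of the helicase that opens DNA for replication, rose by 2.04 (SE 0.11) and 1.54 (SE 0.09). Genes of hypoxia and glycolysis fell for 17 of 22 and rose for 1 (camera adjusted p = 1.1e-05, and adjusted p = 0.308 with an estimated correlation), with P4ha1 at -1.85 (SE 0.09) and Bnip3 at -1.41 (SE 0.08). Imprinted genes fell for 17 of 27 and rose for 4 (camera adjusted p = 0.0033, and adjusted p = 0.412 with an estimated correlation), with Peg10 at -1.99 (SE 0.09). By limma's camera, the stress and immediate early list did not pass (adjusted p = 0.0935, and adjusted p = 0.643 with an estimated correlation, with 12 of 21 members lower and 6 higher), but at the preset correlation it passed without replicate 2 (adjusted p = 0.0421), with median centring without loess (0.0473), without the filter on dim probes (0.0467) and without the genes of chromosomes 8 and 14 (0.0347). Lists of neural crest (6 higher and 6 lower of 16), macrophages (7 and 2 of 14), cartilage and bone (4 and 4 of 13) and epicardium (5 and 4 of 12) did not pass either, with camera adjusted p of 0.823, 0.179, 0.668 and 0.201. Among Y-linked genes, Eif2s3y fell by 1.57 (SE 0.13) while Ddx3y stood at -0.17 (SE 0.12, adjusted p = 0.241), and the X-inactivation RNA Ftx fell by 0.45 (SE 0.08).

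The tests of the authors' value table, of Hopx as labelled, of dye bias, of a uniform delay and of lists without chromosomes 8 and 14 were chosen only after the result was seen. Chromosome 8 stood apart: the median of its 787 genes lay 0.23 above that of all genes (SD 0.031 over the 3 arrays), with 398 genes called higher and 131 lower, and 4 equal runs of its genes in order along it lay at 0.18, 0.24, 0.20 and 0.30. For chromosome 14 the median of 510 genes lay at -0.13, but the last such run stood at -0.36 and the others at -0.10, -0.02 and -0.01. The other 18 chromosomes with over 100 genes lay between -0.04 and 0.04, and 10000 random sets of 787 genes lay between -0.08 and 0.08. Across 16 alternative settings with replicate 3 turned or left out, chromosome 8 lay between 0.09 (no filter on dim probes) and 0.33 (the scanner software's processed signals), and chromosome 14 between -0.16 and -0.04. An additional copy in every cell would give 0.58 if the ratios followed copy number in full. The size of the ratios depended on the background offset. In the main setting 964 genes rose and 1194 fell at least 2-fold, against 1282 and 1476 with the smaller offset of 16. The value expected here may thus lie below 0.58, and 0.23 cannot be judged against it directly.

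The pattern of lower cardiac and endoderm lists and higher early mesoderm, pluripotency and blood lists was weighed against technical and other sources. Gene-specific dye bias is argued against, since 99.6% of the 2126 genes called with at least a 2-fold change on replicates 1 and 2 alone had the same sign on replicate 3, whose dyes run the other way. An extra or lost chromosome stays open as a source, since 0.23 for chromosome 8 lay between the bounds set beforehand and the lines carry the genotypes. These bounds were over 0.3 for a whole-chromosome change and under 0.15 against it. Across the alternative settings the value ran from 0.09, under the lower bound, to 0.33, over the upper, so the verdict depends on the setting. The lists' own members there are argued against as the whole source. All 15 of the 15 lists called at the preset correlation kept that call without chromosomes 8 and 14. The medians moved from 0.72 to 0.44 for neuroectoderm and from -2.40 to -1.79 for the sarcomere. Such shifts depend on which members are left out and do not measure an effect of copy number. Whether copy number plays a part stays open. The later medians cover only members measured on all 3 arrays. The sarcomere's thus also lacks Tnnt2, and its shift is not owed to these chromosomes alone. A uniform delay of differentiation also stays open. Of 82 endothelial, blood and neural genes, 64 rose and 8 fell, the opposite of the joint fall that a delay was taken to predict. Camera at the preset correlation called all 3 of these lists higher. The smallest of their adjusted p values with an estimated correlation was 0.357. That test called 0 of the 27 lists, so it could not decide, and such genes may mark early as well as late stages. Of the 4 choices of the arrays' directions only the choice used gave as many genes (11943, against 0 by limma for the highest other, where at most 61 had an unadjusted p under 0.05, on the probes kept with replicate 3 turned, and 75 on those kept with it as labelled), and 4 choices are too few for a share under 0.05. Since the arrays once turned correlated at r = 0.901 to 0.939, reversing any of them was bound to cancel the calls. The comparison therefore decides nothing about the source. The loss of Hopx itself remains untested apart from the lines.

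That replicate 3 ran against replicates 1 and 2 may reflect an exchange of its cultures or dyes relative to its label, since the authors' own values of that array correlated with its scanner ratios at r = -0.867. A response opposite to the other cultures is argued against by Hopx, which would stand at 3.45 in the culture labelled null on replicate 3 while at -2.98 and -2.97 on replicates 1 and 2.

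DNA of another strain around the inactivated gene could change the genes near Hopx. Of the 50 measured genes on each side of it, 11% changed at least 2-fold, below the 18% that marks the 95th percentile of 12874 such windows and close to their median of 12%, so the data argue against a cluster of such changes there. Smaller changes were not counted, and heterozygous cultures carry the inactivated allele as well, so DNA of another strain as such is not excluded.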
